A study of Sus scrofa with 19 samples.

How the data were processed

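Whole adrenal glands of 19 male piglets, 1 piglet from each sow, were measured on 1-colour Affymetrix arrays. Per the labels' protocols, the sows received control, fish oil or microalgae diets from gestation day 75, and LPS or saline on gestation day 112. Weaning was at 21 days. At 28 days the piglets received LPS themselves, and they were killed 2 hours later. LPS, lipopolysaccharide, is the bacterial cell wall component used to provoke inflammation. Every piglet received LPS, so the arrays hold no gland of an unchallenged piglet. RNA was extracted with the Qiagen RNeasy kit and labelled with biotin by the WT PLUS kit. The submitters' processing notes name Transcriptome Analysis Console 4.0. The summarization and normalization method is not given in the sources used here.

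The deposited values are log2 signals, 1 column per piglet. Base 2 was inferred from their range, 0.263 to 13.5. The array medians lay between 4.38 and 4.52, close but not equal, and the spread differed between arrays. The values were used as deposited, with no further scaling. Of 27558 probe sets, 13157 have 1 gene symbol in the array annotation, 523 have several and 13878 have none. Genes were identified by symbol, after 7 outdated symbols were updated. The annotation used here did not allow the array control probe sets to be identified, so they were not removed, which departs from the plan.

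The 25% of probe sets with the lowest mean log2 value, those under 3.23, were left out (6890). A gene whose mean in some group lies under 3.23 is marked, since its difference is uncertain. After the filter, 20668 were tested, with 10699 carrying 1 symbol. A linear model with 1 mean for each of the 6 groups was fitted in limma 3.58.1 (R 4.3.3), with an intensity trend in the variance prior, 13 residual degrees of freedom and 4.62 prior degrees of freedom. The effect of maternal LPS was the mean over the 3 diets of LPS minus saline. Each diet effect was the mean over both maternal challenges of diet minus control, and fish oil was also set against microalgae. The interactions compared the effect of maternal LPS in each omega-3 diet with that in the control diet, and simple effects compared pairs of groups. All tests were two-sided, with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. The ± values beside differences of genes are standard errors (SE) of the model.

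Gene lists for adrenal function, lipid metabolism, inflammation, stress, energy metabolism and the cell types a whole gland can hold were fixed, and 28 had at least 5 members measured. For each symbol the probe set with the highest mean was used. Lists were tested by limma's camera with a preset correlation of 0.01 between genes, and adjusted over the lists of a comparison. A list described as called passed 0.05 in that test. The ± beside a list's mean difference is the SE between its members. It does not measure the spread between piglets, which can be wider. For interferon-stimulated genes after maternal LPS it was 0.0506, where the SE over piglets, with the array spread as covariate, was 0.156. Camera with an estimated correlation and fry were run beside it, together with an exact permutation test of the list's mean value per piglet, with labels permuted within the levels of the other factor. The permutation test was added after the data were seen, and its smallest possible p is 7.14e-05 for maternal LPS, 0.000816 for fish oil, 0.005 for microalgae and 0.0019 for fish oil against microalgae. For the interactions, diet labels were permuted within each maternal challenge. A medulla score, the mean relative log2 value of 6 measured medulla genes, was taken for each piglet.

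The groups, contrasts, filter, lists, most alternatives and the rule for naming genes were chosen before the data were examined. By that rule, the 10 largest rises and the 10 largest falls past the adjusted threshold are named. Where fewer than 10 genes pass, the 5 largest rises and 5 largest falls at an unadjusted p under 0.01 are named as not past the threshold, or the 10 largest F values for the interaction. Up to 4 members of each called list with the smallest p in the direction of the list are named, and any of 32 fixed adrenal, inflammatory and lipid genes with an unadjusted p under 0.05. Of these 32 genes, 20 were measured and tested here. The other 12, among them STAR, CYP11A1, CYP11B1, MC2R, MRAP, NR5A1, TH, CHGA, IL1B and SOCS3, had no probe set of their own symbol among those tested. Genes named outside the rule are marked as chosen after their values were seen.

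The workflow was tested on simulated data with the design of these 19 arrays and 50 planted changes of each size. For maternal LPS it recovered 25 of 50 changes of 0.50 log2, 47 of 50 changes of 1 log2 and all 50 at 1.5 and at 2 log2, with 9 false calls among 181. A planted shift of 0.30 in a list of 30 members was called and 0 of the 27 other lists were, in simulated data whose genes varied independently. The real arrays do not vary independently, and the number of arrays limits the precision.

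Alternatives were no filter, the lowest 50% left out, quantile normalization, median centring, other variance priors, array weights, the medulla score as covariate, an additive model, other thresholds, only the compared groups in the fit, the mean of all probe sets of a symbol and leaving out each piglet in turn. Camera accepts no robust prior, so for that alternative the preset-correlation test was run on the robust moderated statistics. The alternatives counted for the call of a list all keep camera's preset correlation. The array spread (interquartile range of an array's log2 values) as covariate and the removal of the 2 arrays farthest from the gene-wise medians were added after the data were seen. No paired analysis was possible because the piglets came from different sows and no pairing between groups is given. Probe sets with several symbols or none were tested but not named by gene, and scanner image files were not used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.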

Results

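Adrenal gene expression was measured in 19 male piglets, each from a different sow, 2 hours after the piglets' own LPS challenge. The groups combine the sow's diet with the sow's challenge in late gestation. They hold 3 control-diet piglets after maternal saline (8, 14 and 21 by the labels' numbers) and 3 after maternal LPS (6, 16 and 17). Fish oil has 4 piglets after saline (9, 11, 13 and 18) and 4 after LPS (10, 19, 20 and 24), and microalgae has 3 after saline (12, 15 and 22) and 2 after LPS (7 and 23). Both supplements are sources of long-chain omega-3 fatty acids. Correlations between arrays, across probe sets, ranged from 0.934 to 0.982. The number of arrays limits the precision, and the median SE of the maternal LPS difference was 0.12 log2.

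Signals of steroid hormone synthesis and acute inflammation are given for each gene by its own probe set, and levels cannot be compared between genes. CYP17A1, the enzyme that leads pregnenolone and progesterone toward cortisol and androgens, had group means between 12.21 (microalgae after LPS) and 12.47 log2 (microalgae after saline). HSD3B1 and CYP21A2, enzymes of the same route, had means over all piglets of 11.13 ± 0.302 and 11.22 ± 0.227 (SD, n = 19), and SCARB1, the receptor that takes up cholesterol from HDL, 11.41 ± 0.309. The inflammatory cytokine IL6 had a mean of 10.22 ± 0.856 and the neutrophil attractant CXCL8 one of 10.36 ± 0.49. TNF had 5.18 ± 0.39 and the anti-inflammatory cytokine IL10 3.76 ± 0.247. The medullary enzymes DBH and PNMT, which make noradrenaline and adrenaline, had 6.59 ± 0.678 and 7.14 ± 0.754.

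**Figure D1:**
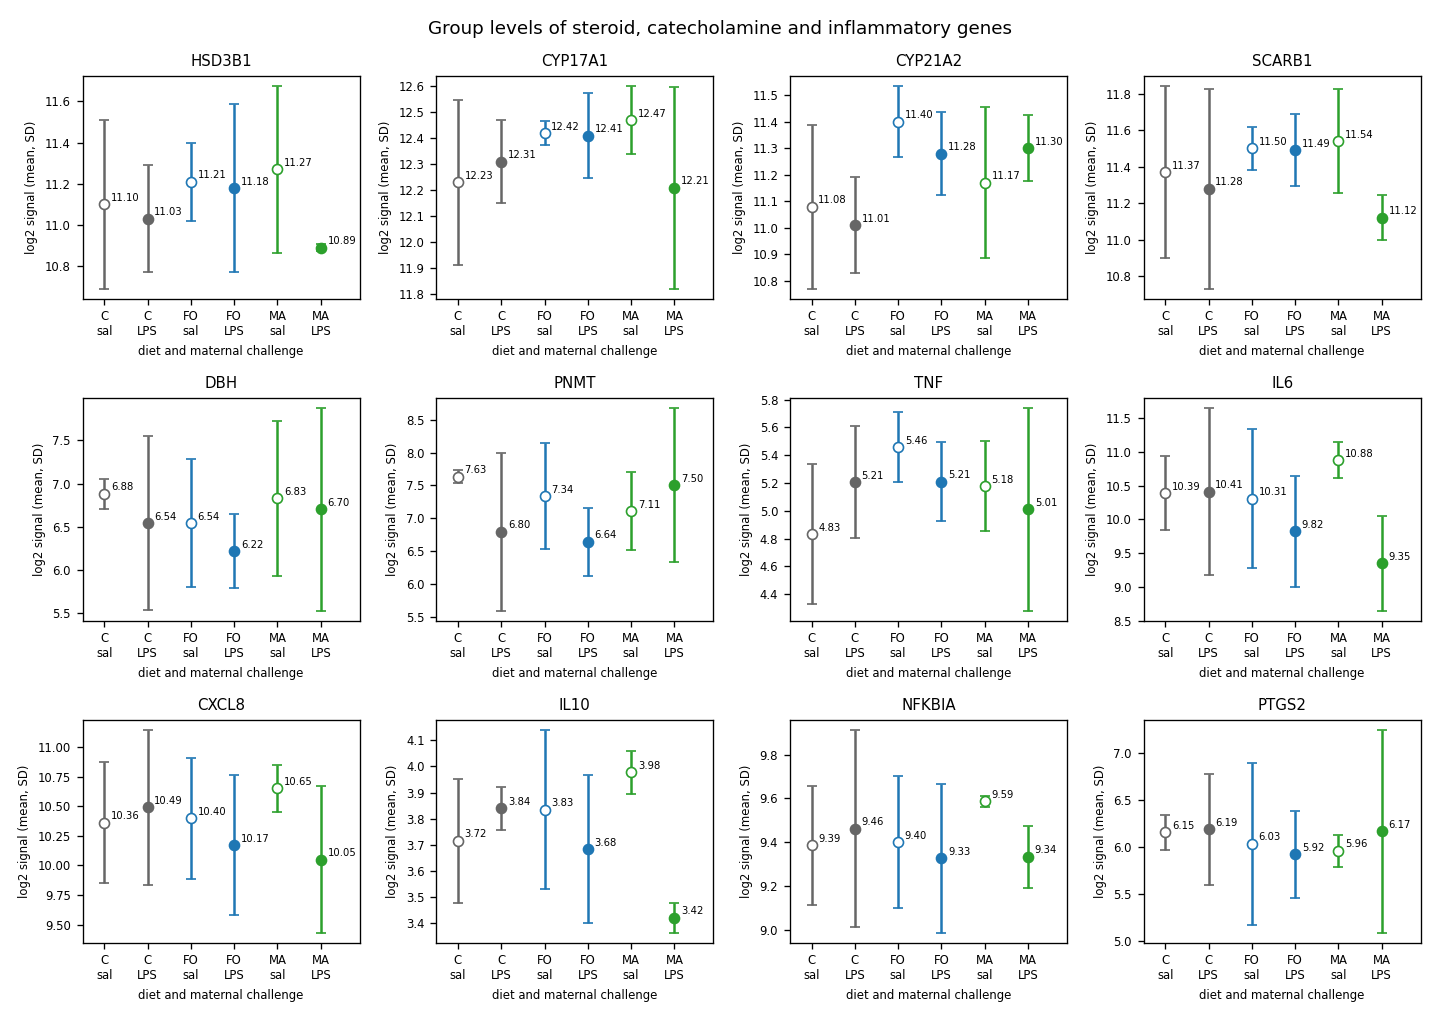
Mean log2 signal (y axis, SD as bars, means printed beside the points) of 12 genes in the 6 groups (x axis: C control, FO fish oil, MA microalgae; sal, maternal saline). CYP17A1 stays between 12.21 and 12.47 in all groups, and IL6 runs from 9.35 in microalgae after LPS to 10.88 in microalgae after saline.

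The effect of maternal LPS on the offspring's adrenal, over the 3 diets, was the first question. Interferon-stimulated genes, the antiviral program that interferons switch on, fell in the offspring of LPS-treated sows, 9 piglets against 10. Of 36 measured, 35 were lower, by a mean of -0.44 ± 0.0506 log2, most of it in fish oil offspring. The mean was -0.13 in control (exact permutation p 0.3), -0.96 in fish oil (exact permutation p 0.0286) and -0.22 in microalgae offspring (exact permutation p 0.6). Adjusted over the list alone, 11 members fell. Adjusted over all probe sets 0 members passed (0.169 for IFIT2 and 0.419 for CXCL11). IFIT2 (-1.26 ± 0.261), IFIT3 (-0.88 ± 0.22) and IFIT1 (-0.72 ± 0.162) act against viral RNA. The others were the chemokines CXCL11 (-1.29 ± 0.362) and CXCL9 (-0.84 ± 0.292), the RNA sensor IFIH1 (-0.40 ± 0.106), and GBP1, CMPK2, PARP14, TRIM21 and ZBP1. Of these 11, CXCL9, GBP1, CMPK2, PARP14, TRIM21 and ZBP1 are named after their values were seen. The camera test gave an adjusted p of 5.96e-20. Unadjusted, the list had p = 0.0304 with an estimated correlation and 0.0153 by exact permutation. Adjusted over the 28 lists these were 0.426 and 0.214, so the call was lost in both. The exact permutation p was 0.10 without piglet 23, where the shift was -0.32, and stayed at or below 0.0462 without any other single piglet.

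**Figure D2:**
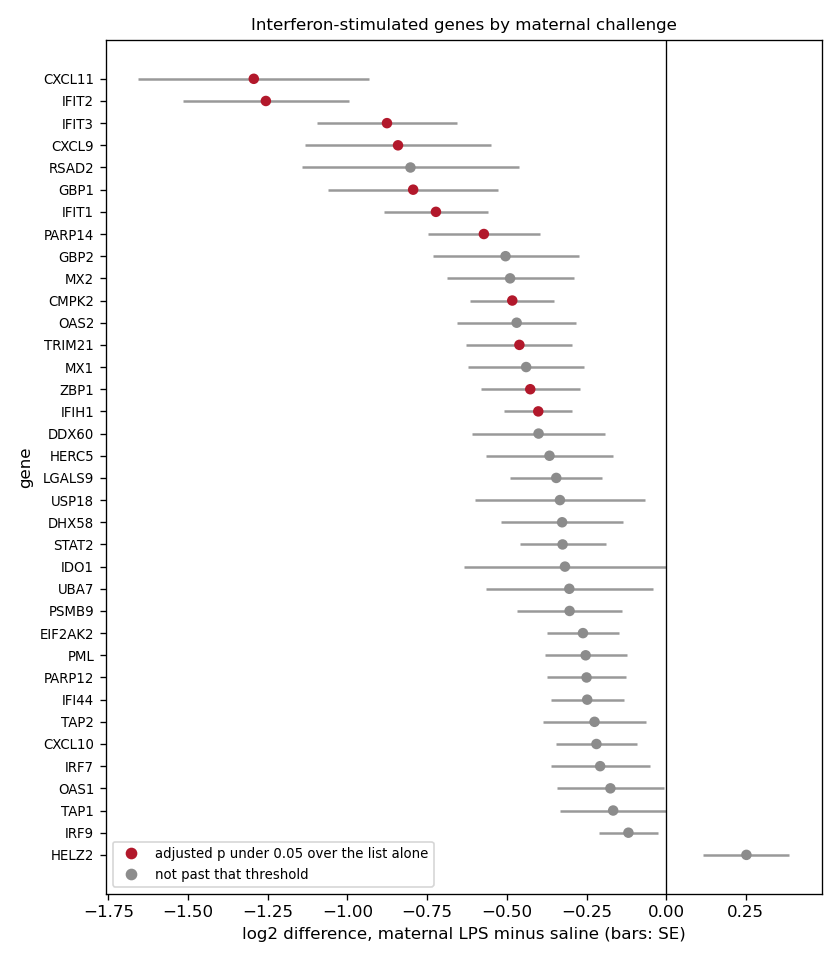
Log2 difference between piglets of LPS-treated and saline-treated sows (x axis, SE as bars) for the 36 interferon-stimulated genes (y axis). Genes past an adjusted p of 0.05 over the list alone are red: 11 genes, all lower, from CXCL11 (-1.29) to IFIH1 (-0.40), while 1 gene lies above 0.

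The list of receptors and adaptors that sense microbes was lower on average over the diets, but not in the control diet. The fall was not general: the median was -0.06 and 10 members were higher. TLR4 and CD14, which sense LPS and are named after their values were seen, had -0.03 ± 0.172 and 0.11 ± 0.137. Of 27 such genes 17 were lower (mean -0.10 ± 0.0477, camera adjusted p 0.0434; unadjusted, p = 0.0479 with an estimated correlation, 0.0461 by exact permutation). The mean was 0.04 in control offspring (14 of 27 higher), -0.15 in fish oil offspring and -0.21 in microalgae offspring. Adjusted over the lists, the call was lost with an estimated correlation (0.447) and by exact permutation (0.43). TLR3, the receptor for double-stranded RNA (-0.94 ± 0.182), IRAK4 (-0.48 ± 0.127) and MYD88 (-0.37 ± 0.112), which pass on Toll-like receptor signals, fell with adjusted p values over the list alone of 0.00186, 0.0188 and 0.0351. Adjusted over all probe sets 0 members of the sensing list passed (0.116 for TLR3). The adaptor TICAM2 had -0.41 ± 0.155. Cell proliferation genes were lower too, 13 of 15 (-0.14 ± 0.0321, camera adjusted p 0.000719; unadjusted, p = 0.0143 with an estimated correlation, 0.006 by exact permutation). Adjusted over the lists, that call was lost too (0.4 and 0.168). NCAPG (-0.32 ± 0.0979) and ANLN (-0.30 ± 0.0953), needed to condense chromosomes and divide the cell, passed the threshold adjusted over the list alone. Their group means, from 3.11 to 3.86, lie at the level of 3.23 under which probe sets were left out, so these falls are uncertain. TOP2A had -0.34 ± 0.15 and TPX2 -0.23 ± 0.11. The call of the sensing list was lost without any 1 of piglets 6, 8, 18, 20, 22, 23 and 24, with shifts from -0.12 to -0.08 over all 19 such fits, and held in 5 of 11 alternatives (lost with the lowest 50% left out, quantile normalization, median centring, array weights, the array spread, and without piglets 6 and 24). The proliferation call held in all 19 such fits and in the 10 alternatives that could test it.

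Genes of antigen presentation were lower in 19 of 21 cases (-0.16 ± 0.0277, camera adjusted p 0.000719), a call lost with an estimated correlation (unadjusted p = 0.142). Among them were SLA-DRA (-0.34 ± 0.136), SLA-3, TAPBP and the peptide trimming enzyme ERAP1 (-0.27 ± 0.115). Cholesterol synthesis genes were lower in 15 of 16 cases (-0.19 ± 0.0255, camera adjusted p 0.00456), a call lost with an estimated correlation (unadjusted p = 0.264). FADS1, a desaturase of polyunsaturated fatty acids, was at -0.38 ± 0.171, SC5D at -0.34 ± 0.239, MVK at -0.21 ± 0.145 and LPIN1 at -0.17 ± 0.115. Of 49 acute inflammatory genes 36 were lower (-0.09 ± 0.0258, camera adjusted p 0.0436), a call lost with an estimated correlation (unadjusted p = 0.224). They included CD83 (-0.38 ± 0.139), CH25H (-0.36 ± 0.146), VCAM1 (-0.24 ± 0.127) and IL6 (-0.66 ± 0.352). In control offspring the inflammatory list had a mean of 0.03, with 28 of 49 higher. By group means IL6 and VCAM1 were not lower in control offspring, MVK not in fish oil offspring and LPIN1 not in microalgae offspring. The neutrophil protein S100A9, named after its values were seen, was higher at 0.32 ± 0.0963. No member of these 3 lists passed the threshold adjusted over the list alone. The cholesterol call was also lost without any 1 of piglets 6, 8, 12 and 23 (-0.27 to -0.09), with the lowest 50% left out and without both piglets 6 and 24. The inflammatory call was lost without any 1 of piglets 6, 7, 8, 10, 12, 13, 15, 18 and 24 (-0.12 to -0.05). It held in 4 of 11 alternatives, being lost with the lowest 50% left out, quantile normalization, median centring, array weights, the array spread, the mean of all probe sets, and without both piglets 6 and 24.

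Among single genes, 2 probe sets without a gene symbol passed limma's threshold over all 20668 tested, both lower in all 3 diets: 15217337 at -1.04 ± 0.159 and 15327286 at -0.91 ± 0.136, each with an adjusted p of 0.0409. The largest rises at an unadjusted p under 0.01 were those of TAF7 (0.95 ± 0.264), a subunit of the general transcription factor TFIID, RASL11A (0.65 ± 0.19), the keratin KRT5 (0.53), the vessel destabilising factor ANGPT2 (0.50) and BNIPL (0.49), with adjusted p from 0.413. KRT5 and ANGPT2 had group means under 3.23, so their sizes are uncertain. The largest falls outside the lists above were POSTN, a matrix protein (-1.32 ± 0.455, adjusted p 0.605; in fish oil offspring it was higher, 6.94 after saline and 7.22 after LPS), and ATAD2, a chromatin regulator (-0.90 ± 0.203, adjusted p 0.238). TMEM100 (-0.71) and PRRG4 (-0.70), named after their values were seen, had an adjusted p of 0.0927. The counts at an unadjusted p under 0.05 were 697 higher and 743 lower, and 389 and 1122 after median centring. The calls were fragile. In limma 0 passed without a filter, after quantile normalization, in an additive model or with the medulla score or the array spread as covariate, 9 passed with array weights. Leaving out 1 piglet gave 12 without piglet 7, 2 without piglet 14, 1 without any 1 of piglets 10, 15, 17 and 24, and 0 without any other.

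Maternal fish oil, set against the control diet in 8 and 6 piglets, went with lower expression of connective tissue genes. Of 23 fibroblast and capsule markers 20 were lower (-0.40 ± 0.0819 log2), and the collagens COL5A2 (-0.43 ± 0.108) and COL6A3 (-0.49 ± 0.136) fell with adjusted p over the list alone of 0.0221 and 0.0243. The main fibrillar collagens had differences of -1.06 (COL1A1, named after its values were seen), -0.93 ± 0.351 (COL1A2) and -0.84 ± 0.29 (COL3A1). Markers of leucocytes were higher. For macrophages they were 19 of 20 (0.15 ± 0.0254), with the mannose receptor MRC1 at 0.38 ± 0.198, ITGAM at 0.32, CD86 at 0.25 and MS4A7 at 0.27. That rise was seen after maternal saline (0.39, 19 of 20 higher, exact permutation p 0.0857) and not after maternal LPS (-0.10, 11 of 20 lower, exact permutation p 0.371). For lymphocytes they were 16 of 21 (0.14 ± 0.0401), with NKG7 of cytotoxic cells at 0.37 ± 0.111, CD2 at 0.54 ± 0.23, CD5 at 0.32 and GZMA at 0.42. MRC1 likewise was higher only after saline, and GZMA had group means under 3.23. Antigen presentation genes were higher in 17 of 21 cases (mean 0.135 ± 0.0349), including the class II genes SLA-DOB (0.52), SLA-DQB1 (0.27), SLA-DQA1 (0.26) and SLA-DRB1 (0.30, higher only after maternal LPS).

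Mitochondrial and redox genes were higher with fish oil too. Of 28 oxidative phosphorylation genes 23 were higher (mean 0.105 ± 0.0157), among them COX6A1 (0.19), NDUFA9 (0.21), ATP5B (0.18) and NDUFA1 (0.31). Of 26 antioxidant genes 19 were higher (0.08 ± 0.0281), with PRDX6 at 0.33 ± 0.13 and NQO1 at 0.28 ± 0.119, and GSR at 0.22 and CAT at 0.30. Of 27 fatty acid oxidation genes 19 were higher (0.07 ± 0.0234). CPT2 (0.33 ± 0.137) and SLC25A20 (0.31 ± 0.129) carry fatty acids into mitochondria, and ACADS (0.24) and ACADL (0.19) start their breakdown. Camera called these 7 lists with adjusted p from 9.54e-09 (fibroblast) to 0.0399 (fatty acid oxidation). All 7 calls were lost with an estimated correlation, with p = 0.0663 for fibroblast, p = 0.125 for macrophage, p = 0.0972 for lymphocyte and p = 0.203 for antigen presentation genes. With an estimated correlation, limma's camera gave p = 0.148 for oxidative phosphorylation, p = 0.0821 for antioxidant and p = 0.0551 for fatty acid oxidation genes. Leaving out 1 piglet ended the antigen presentation call (piglets 10, 18 and 24; 0.09 to 0.19) and the antioxidant call (piglet 6; 0.04 to 0.12). The fibroblast shift ran from -0.61 (without piglet 6) to -0.26 (without piglet 8), and the oxidative phosphorylation shift from 0.06 (without piglet 10) to 0.14 (without piglet 18), both still called. Leaving out 1 piglet also ended the lymphocyte call (piglet 24; 0.10 to 0.18) and the fatty acid oxidation call (piglets 6, 8, 10, 13, 17 and 20; 0.03 to 0.10). The fatty acid oxidation call held in 5 of 11 alternatives, being lost with quantile normalization, median centring, array weights, the medulla score, the array spread, and without both piglets 6 and 24. The antioxidant call was lost with quantile normalization, the array spread and without both piglets, and the lymphocyte call with array weights and without both piglets.

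Of single genes, 0 passed limma's threshold for fish oil, where 555 had an unadjusted p under 0.05, 288 higher and 267 lower (362 and 207 after median centring), and all genes named here had an adjusted p of 1. The largest rises were those of the potassium channel KCNK9 (0.84 ± 0.29, with both control groups under 3.23, so its size and place are uncertain), of HSD11B2, which inactivates cortisol (0.53 ± 0.166), and of TSPAN1 (0.52 ± 0.126, also with a control group under 3.23), PRR19 (0.50) and LOC100512420 (0.49). The largest falls were those of PTX3, a secreted pattern recognition protein of innate immunity (-1.0 ± 0.297), CNIH3 (-0.56) and ANKS4B (-0.38), beside the collagens. The steroid enzyme CYP21A2 was 0.30 ± 0.119 higher (unadjusted limma p 0.0232).

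Maternal microalgae, set against the control diet in 5 and 6 piglets, went with higher expression of cholesterol synthesis genes. Of 16 such genes 15 were higher (0.28 ± 0.0435), including the cholesterol carrier STARD4 (0.57 ± 0.31), HMGCS1 (0.50 ± 0.312) and SQLE (0.47 ± 0.278) of the synthesis route, and FADS1 (0.38 ± 0.222). Lymphocyte markers were higher in 17 of 21 cases (0.12 ± 0.0268), with CD5 at 0.35, NKG7 at 0.21 (higher only after saline), CD8B at 0.18 and CD3D at 0.25. Endothelial markers were lower in 14 of 17 cases (mean -0.105 ± 0.0292), with CD34 at -0.35 ± 0.114, ECSCR at -0.29 ± 0.133, TEK at -0.21 (0.02 without piglet 7) and PECAM1 at -0.15. Camera's adjusted p values were 4.05e-05, 0.00316 and 0.00428, and no member of these lists passed adjusted over the list alone. All 3 calls were lost after adjustment with an estimated correlation, where the unadjusted values were p = 0.123, p = 0.0893 and p = 0.0294. The endothelial list had an adjusted 0.822 there, and 0.10 unadjusted by exact permutation. The cholesterol call was lost without piglet 6 (0.13 to 0.37), the lymphocyte call without piglet 15 (0.075 to 0.17) and the endothelial call without any 1 of piglets 7, 8, 15 and 22 (-0.15 to -0.07). Of 11 alternatives, 1 ended each call: leaving out both piglets 6 and 24 (cholesterol), leaving out the lowest 50% (lymphocyte) and array weights (endothelial).

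For microalgae 0 genes passed limma's threshold, with 340 at an unadjusted p under 0.05, 177 higher and 163 lower, which turned to 143 and 215 after median centring. The largest rises were those of the protease inhibitor SPINK5 (1.14 ± 0.374), the class II chaperone SLA-DOB (0.81), RASL12 (0.56), PPP1R18 (0.50, with another probe set in the other direction) and LOC100153661 (0.47). The largest falls were those of the glycosyltransferase MGAT4C (-1.14 ± 0.286), MIR105-2 (-0.73), the retinol dehydrogenase RDH5 (-0.71), LSG1 (-0.66) and LOC100520401 (-0.53), all with an adjusted p of 1. MIR105-2 and RDH5 had a group mean under 3.23, so their sizes are uncertain.

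Set against each other in 8 and 5 piglets, fish oil went with higher mitochondrial, fatty acid oxidation and vessel genes than microalgae. Oxidative phosphorylation genes had a mean difference of 0.12 (NDUFA9 0.26, SDHD 0.25, COX6A1 0.19, NDUFB3 0.25), fatty acid oxidation genes 0.10 (PPARG, the adipogenic lipid receptor, 0.39 ± 0.143; SLC25A20 0.36, ACADS 0.24, ACADL 0.26) and endothelial markers 0.13. CD34, the vessel surface protein, was higher by 0.47 ± 0.107 (adjusted over the list alone, 0.00671), and TEK by 0.35, KDR by 0.30 and ESAM by 0.27. Macrophage markers (0.14, with MRC1 0.57, MS4A7 0.46, CSF1R 0.25 and SPI1 0.18) and antioxidant genes (0.11, with SRXN1 0.40, PRDX6 0.34, PRDX2 0.19 and MSRA 0.42) were higher as well. So were antigen presentation genes (0.08, with SLA-DQA1 0.51, SLA-DQB1 0.39, SLA-DRA 0.31 and SLA-DRB1 0.32) and cytosolic ribosomal proteins (0.06, with RPL35 0.14, RPS16 0.12, RPS24 0.18 and RPL3 0.12). Lower with fish oil were fibroblast markers (-0.31, with COL6A3 -0.40, MFAP5 -0.93, COL3A1 -0.63 and COL1A1 -1.01) and cholesterol synthesis genes (-0.20, with FADS1 -0.42, SQLE -0.50, STARD4 -0.38 and HSD17B7 -0.23). Also lower were chromaffin cell genes (-0.20; the peptide CARTPT -1.53 ± 0.673, SLC18A1 -0.41, PCSK2 -0.22, ISL1 -0.32) and interferon-stimulated genes (-0.11; IFIH1 -0.26, PARP12 -0.24, EIF2AK2 -0.21, PSMB9 -0.29). By group means, several of these differences varied with the maternal challenge, but whether they depended on it was not tested. Interferon-stimulated genes were higher with fish oil after saline (mean score 0.44 against 0.18) and lower after LPS (-0.52 against -0.05). Fibroblast markers had mean scores of -0.37 against 0.23 after saline (SD 0.31 and 0.34). After LPS the mean scores were -0.07 against -0.04 (SD 0.52 and 0.17). In these means antioxidant genes turned direction, the gap of antigen presentation genes lay after saline, and that of ribosomal proteins lay almost wholly after LPS. By group means PARP12, EIF2AK2, PSMB9, MFAP5, SLC18A1, ACADL, SLA-DRA, SLA-DRB1, MSRA, SDHD, NDUFB3, RPL35, RPS16 and RPS24 took opposite directions after saline and after LPS. PPARG and MFAP5 had a group mean under 3.23. Medulla scores differed by -0.29 (exact permutation p 0.347), and the chromaffin call was lost with the medulla score as covariate, so a different share of medulla is not excluded.

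Camera called these 11 lists with adjusted p from 5.4e-05 (oxidative phosphorylation) to 0.0427 (antigen presentation). All 11 calls were lost after adjustment with an estimated correlation. Unadjusted, with an estimated correlation, the endothelial list had p = 0.022 and the fatty acid oxidation list p = 0.0152, both 0.307 adjusted, and by exact permutation they had 0.0533 and 0.0381, both 0.746 adjusted. The other unadjusted values with an estimated correlation were p = 0.104 for oxidative phosphorylation, p = 0.158 for macrophage, p = 0.0861 for antioxidant and p = 0.364 for antigen presentation genes. With an estimated correlation limma gave p = 0.211 for ribosomal, p = 0.207 for fibroblast, p = 0.276 for cholesterol, p = 0.27 for chromaffin and p = 0.47 for interferon-stimulated genes. The oxidative phosphorylation call held in all 19 fits without 1 piglet, from 0.08 (without piglet 7) to 0.17 (without piglet 23). The interferon list turned to 0.07 without piglet 7 and 0.02 without piglet 20, and its call was also lost without any 1 of piglets 11, 12 and 13. Further calls were lost without piglet 7 (fatty acid oxidation, 0.07 to 0.14), piglets 7 and 15 (antioxidant, 0.08 to 0.14), piglets 7, 12 and 13 (cholesterol, -0.30 to -0.08), piglet 22 (macrophage, 0.07 to 0.22) and piglet 24 (fibroblast, -0.38 to -0.19). The same held for piglets 7, 9, 10, 11, 12 and 13 (ribosomal, 0.02 to 0.11), piglets 7, 12, 13, 18, 20 and 24 (chromaffin, -0.36 to -0.03) and piglets 6, 9, 10, 18, 22, 23 and 24 (antigen presentation, 0.02 to 0.14), each left out alone. Of 11 alternatives, 7 kept the chromaffin call (lost also with array weights, the array spread and without both piglets 6 and 24), and 9 the interferon call (lost with the medulla score and the array spread). The macrophage call was kept by 9 (lost with array weights and without both piglets), the ribosomal by 8 (lost with the lowest 50% left out, quantile normalization and the array spread) and the antioxidant by 10 (lost with the array spread). Antigen presentation kept its call in 5, losing it without a filter, with the lowest 50% left out, quantile normalization, median centring, array weights and without both piglets. Among single genes 0 passed limma's threshold and 590 had an unadjusted p under 0.05, 321 higher with fish oil and 269 lower, or 502 and 158 after median centring. The largest rises were HSD11B2 (0.59 ± 0.177), LOC100155267 (0.54), LSG1 (0.54), the dendritic cell marker CD83 (0.53) and BCKDK (0.51). The largest falls were EPHB2 (-0.56), HAPLN3 (-0.51), LOC100153661 (-0.50), AOC2 (-0.49) and LOC100523020 (-0.48, lower only after maternal LPS). LOC100155267 and AOC2 had a group mean under 3.23.

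Whether the diet alters the effect of maternal LPS is the question of the interactions. For fish oil, interferon-stimulated genes differed most. After maternal LPS they were lower by -0.96 in fish oil offspring (35 of 36 lower, exact permutation p 0.0286, the smallest possible), against -0.13 in control offspring (27 of 36 lower, exact permutation p 0.3, where 0.1 is the smallest possible). Against control offspring, fish oil offspring had 0.39 after saline (34 of 36 higher, exact permutation p 0.0571) and -0.44 after maternal LPS (all 36 lower, exact permutation p 0.2). The interaction of -0.83 ± 0.0656 (camera adjusted p 4.79e-25; unadjusted, p = 0.0174 with an estimated correlation, permutation p 0.0098) lost its call after adjustment over the lists (0.314 and 0.274). It included DDX60 (-1.42 ± 0.477), LGALS9 (-0.98), PARP12 (-0.88) and IFIH1 (-0.70). In limma 0 members passed the threshold adjusted over the list alone and 13 had an unadjusted p under 0.05. The permutation p was 0.059 without piglet 6, and the difference was -0.57 without piglet 20. In microalgae offspring the genes had -0.22 after maternal LPS (24 of 36 lower, exact permutation p 0.6), and the microalgae interaction was -0.09 (17 higher, 19 lower, camera adjusted p 0.714).

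Macrophage markers had a mean difference after maternal LPS of 0.32 in control offspring (18 of 20 higher, exact permutation p 0.1). It was -0.17 in fish oil offspring (15 of 20 lower, exact permutation p 0.4) and -0.18 in microalgae offspring (17 of 20 lower, exact permutation p 0.6). The differences from control were -0.49 for fish oil (camera adjusted p 8.61e-08; unadjusted, p = 0.0248 with an estimated correlation, permutation p 0.0506) and -0.50 for microalgae (0.000314; unadjusted, p = 0.0775 with an estimated correlation, permutation p 0.025). Adjusted over the lists, both calls were lost with an estimated correlation (0.314 and 0.935) and by permutation (0.708 and 0.70). The complement gene C1QC (-1.29 and -1.62), the scavenger receptor MSR1 (-0.79 and -0.80) and MRC1 (-0.90 and -1.12) led both, with C1QA (-0.89) for fish oil and CSF1R (-0.61) for microalgae. Both interactions subtract the effect in the same control piglets. Similar sizes and shared leading genes, here and in the sensing list, are therefore partly built in. The sensing list moved the same way (-0.19 for fish oil, unadjusted p = 0.0337 with an estimated correlation, permutation p 0.0898; -0.25 for microalgae, unadjusted p = 0.0291 with an estimated correlation, permutation p 0.055). After adjustment its calls were lost in both. It was led by LY96, the LPS-binding partner of TLR4 (-1.13 ± 0.33 and -1.32 ± 0.374). TLR3 (-0.94), TLR2 (-0.44) and TNIP1 (-0.38) followed for fish oil and TLR2 (-0.50), TLR7 (-0.56) and TLR10 (-0.53) for microalgae, with another probe set of TLR2 in the other direction in both. The acute inflammatory list differed by -0.19 for fish oil, with CCL4 (-0.66), TNF (-0.62), SELE (-0.56) and CCL2 (-0.55), and its call (camera adjusted p 0.0265) was lost with an estimated correlation (unadjusted p = 0.168). Both sensing calls (camera adjusted p 0.0265 and 0.0391) were lost without any 1 of piglets 16, 17, 21 and 24, the fish oil one also without 18 (range -0.28 to -0.14) and the microalgae one without 12, 22 or 23 (-0.34 to -0.21). The inflammatory call was lost without any 1 of piglets 10, 16, 17, 18 and 24 (-0.33 to -0.11). Quantile normalization and the mean of all probe sets ended it as well. That mean also ended both sensing calls, and the microalgae one was further lost with the lowest 50% left out, quantile normalization, the medulla score and the array spread.

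In the F test of both interactions 0 genes passed limma's threshold and 982 had an unadjusted p under 0.05. The largest F values were those of the choline kinase CHKA (14.2), MGARP (12.4), the phagocyte oxidase subunit GP91-PHOX (11.2), FBXL6 (10.1), the meiotic cohesin REC8 (9.82), FAM129A (9.72), SBSPON (9.70), C13H21orf91 (9.36), SLA-DRB1 (9.18) and VASH2 (8.81), all with an adjusted p of 0.972. CHKA had 5.75 ± 0.138 after saline and 7.09 ± 0.234 after LPS in microalgae offspring (SD, n = 3 and 2), against 6.64 ± 0.2 and 6.41 ± 0.463 in control offspring. Of the fixed genes, HSD11B1, which regenerates cortisol (-0.87, unadjusted limma p 0.0374), and IL10 (-0.68, unadjusted limma p 0.03) are named for the microalgae interaction, with an adjusted p of 0.858. Counts at an unadjusted p under 0.05 were 545 for the fish oil interaction (215 higher, 330 lower) and 1118 for the microalgae interaction (593 higher, 525 lower, or 384 and 721 after median centring), with 0 past limma's threshold in each. Within single diets maternal LPS gave 0 in limma, with 359 at an unadjusted p under 0.05 in control offspring, 883 in fish oil offspring (287 higher, 596 lower) and 2411 in microalgae offspring (1211 higher, 1200 lower, or 676 and 1811 after median centring). The 2411 rest on 3 and 2 piglets and were not tested against chance, so they do not show a larger response. Leaving out piglet 7 or 23 gave 2 calls in fish oil offspring, and leaving out piglet 7 or 10 gave 3 and 1 in microalgae offspring. Within maternal saline, limma called 0 genes for fish oil (441 at an unadjusted p under 0.05) and 0 for microalgae (563), and within maternal LPS 0 for fish oil (691) and 0 for microalgae (752), with 1 for fish oil within maternal LPS without piglet 24.

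**Figure D3:**
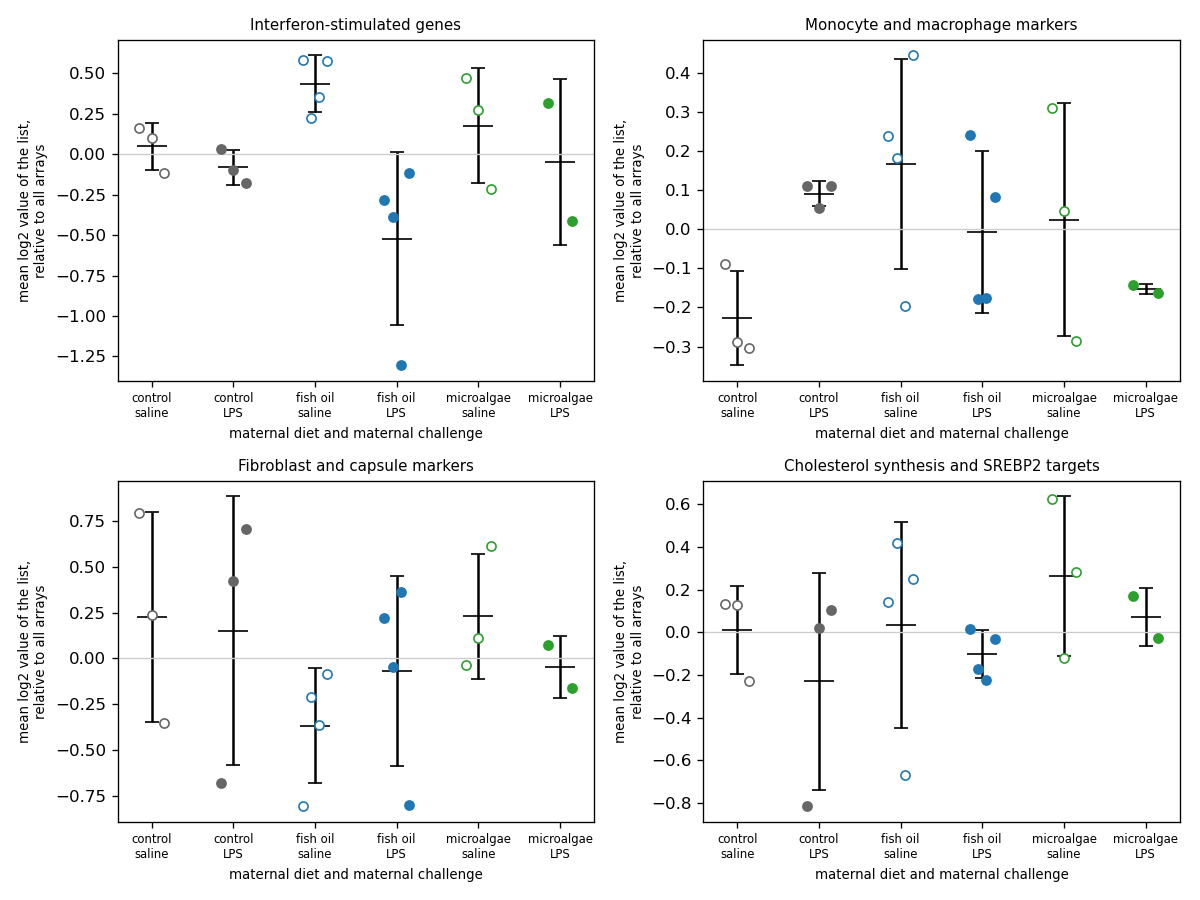
Mean log2 value of 4 gene lists relative to all arrays (y axis), 1 point per piglet, by maternal diet and maternal challenge (x axis), with the group mean and SD as bars. Interferon-stimulated genes average 0.44 in fish oil offspring after saline and -0.52 after LPS, and macrophage markers -0.23 and 0.09 in control offspring.

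**Figure D4:**
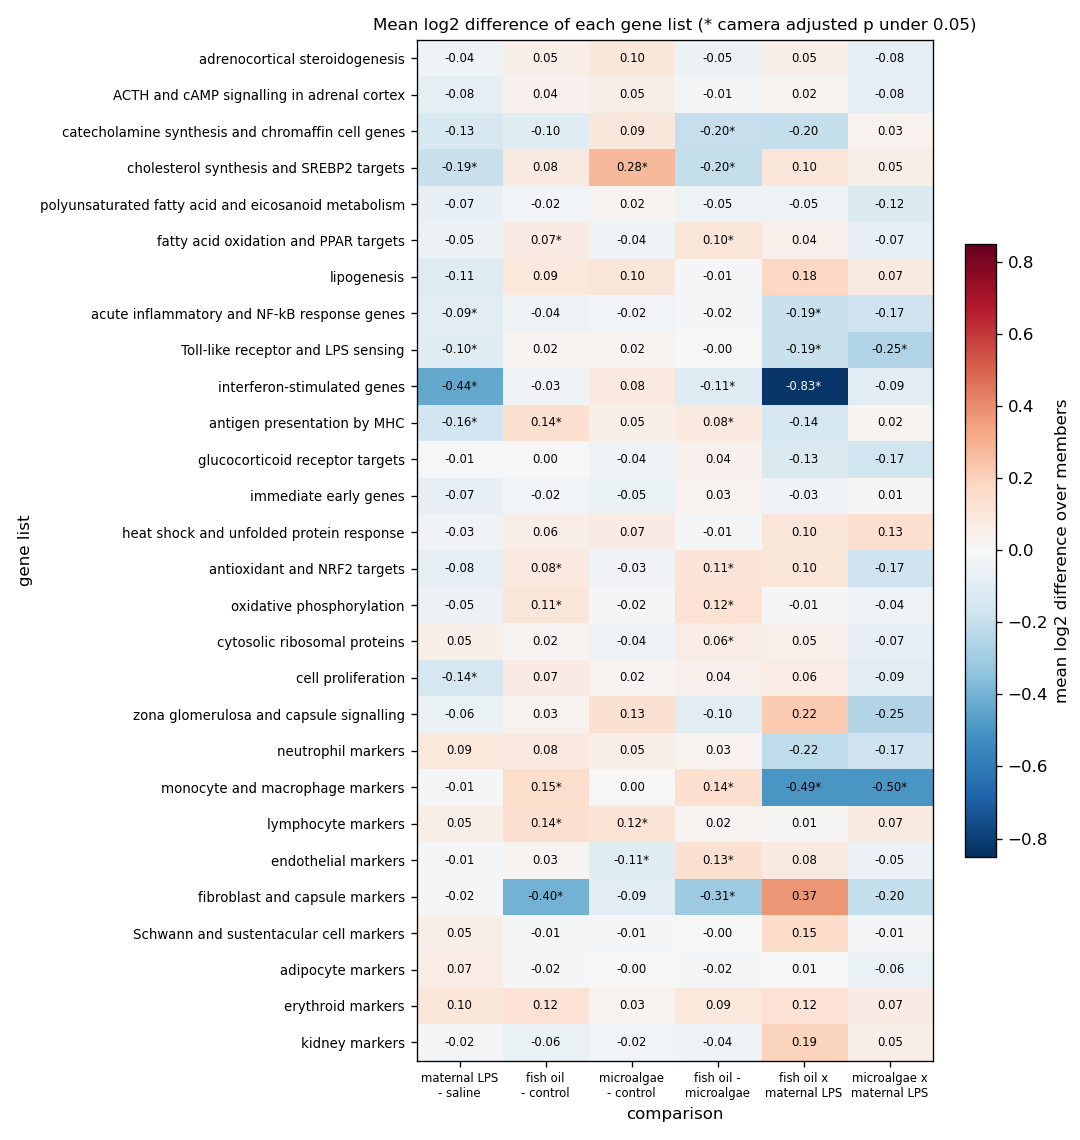
Mean log2 difference over the members (colour and printed value) of the 28 gene lists (y axis) in 6 comparisons (x axis), with an asterisk at a camera adjusted p under 0.05. Interferon-stimulated genes reach -0.44 for maternal LPS and -0.83 for the fish oil interaction.

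With Benjamini-Hochberg adjustment over the 28 lists, 0 lists passed in any of the 6 comparisons by camera with an estimated correlation, by limma's fry for a common direction or by permutation. Camera with the preset correlation called 6, 7, 3, 11, 4 and 2 in the order above, and fry for changes in either direction called 1 list for maternal LPS and 0 elsewhere. The arrays themselves differed in spread, and the leading principal component (24.4% of the variance) followed that spread over the 19 arrays (Pearson's r 0.832, permutation p 2e-05 over 1e+05 permutations; Spearman's rho 0.763, permutation p 0.00034; r 0.686 without the 2 most extreme arrays). The spread differed by -0.07 between piglets of LPS-treated and saline-treated sows (exact permutation p 0.15), and the medulla score by -0.16 (exact permutation p 0.556), by -0.22 for fish oil (exact permutation p 0.451) and by 0.07 for microalgae (exact permutation p 0.85). In microalgae offspring, both arrays after LPS lay lower on the leading principal component (-23.8 and -18.6) than those after saline (10.2, -0.135 and 40.2). Array differences and maternal LPS cannot be told apart there. Across probe sets, which are not independent replicates, the effects of fish oil and microalgae correlated with r = 0.432 when sharing control piglets, where simulated unchanged groups gave a median of 0.553, and with 0.0934 and -0.0677 without shared piglets. The effect of maternal LPS correlated between diets with 0.0347 (control and fish oil), 0.0854 (control and microalgae) and 0.0692 (fish oil and microalgae). Piglets shuffled within diets gave 95% ranges of -0.332 to 0.301, -0.37 to 0.363 and -0.472 to 0.371. For the diet effects without shared piglets, simulated unchanged groups gave -0.385 to 0.479 and -0.461 to 0.445. Ranges this wide cannot tell shared from separate effects.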

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

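The tests of a single piglet behind a pattern and of a weaker response to the piglet's own LPS were chosen after the results were seen. SE values in this section are over piglets, apart from the one marked as between members.

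Interferon-stimulated genes were lower after maternal LPS by -0.44 log2 over 36 genes, mostly in fish oil offspring (-0.96, against -0.13 in control and -0.22 in microalgae offspring). A correction for array spread left the shift at -0.54 (SE 0.156), which argues against the spread as its whole cause. A correction for macrophage and lymphocyte scores left it at -0.46 (SE 0.15). That argues against leucocyte content as the whole cause of the mean over the 3 diets only. Macrophage markers were higher in control (0.32) and lower in fish oil (-0.17) and microalgae offspring (-0.18), and nearly cancelled in that mean (-0.01). Leucocyte content was not tested within fish oil offspring, where most of the fall lay. A part played by 1 piglet stays open, since the shift was -0.32 with an exact permutation p of 0.10 without piglet 23, the highest p in the 19 fits. A weaker response to the piglet's own LPS may account for part of the pattern and cannot be told apart from a specific change, because the acute inflammatory list, which shares no member with the interferon list, shifted by -0.0945 (SE 0.0667), neither under 50% of the interferon shift by over 2 SE nor at that size. An effect of the mother's challenge is the biological explanation that the design offers, and it stays open.

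The same genes gave a difference of -0.827 between the effects of maternal LPS in fish oil and control offspring, tested by the interaction itself. With the array spread as covariate the difference was -0.811 (SE 0.336), which argues against the spread as its whole cause. Without piglet 20 the difference was -0.566, still over 50% of its size, but without piglet 6 its permutation p was 0.059, so a part played by 1 piglet stays open. An effect of the diet stays open as the biological explanation: against control offspring, fish oil offspring had 0.39 after saline (exact permutation p 0.0571) and -0.44 after maternal LPS (exact permutation p 0.2). Macrophage markers differed in the same interaction (-0.493), and a correction for leucocyte scores was not run for this difference, so leucocyte content stays open too.

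Fibroblast and capsule markers were lower with fish oil by -0.40 over 23 genes. The 16 members that are not collagens had a median of -0.38 (SE of their mean, between members, 0.0902), beside -0.49 for the 7 collagens. The list's members varied together within groups (mean r 0.499 across pairs of genes, where 95% of 1000 random lists lay under 0.0992). A different share of connective tissue in the glands is therefore a candidate explanation. The array spread left the shift at -0.51 (SE 0.213), which argues against it as the whole cause. Leaving out 1 piglet left at least -0.26 (without piglet 8), over 50% of its size. By size alone, this argues against any single piglet as the whole cause. The interferon patterns were also judged by their permutation p, a rule not applied here. The exact permutation p of the fibroblast shift was 0.173 over all piglets, so a part played by 1 piglet stays open. A biological effect of the diet on connective tissue stays open beside a different share of tissue.

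Other splits of the same piglets show how far chance can be excluded. Of 100 splits, 3, the real one included, gave at least the 2 probe sets past the adjusted threshold of maternal LPS. That share is not adjusted over the split tests, other settings bring the count to 0, and another split gave 212. Chance is therefore not excluded for the count, and what made 212 probe sets pass in that split was not tested. At an unadjusted p under 0.05, chance was not excluded for maternal LPS (24 of 100 splits as large; 1440 real, 4195 highest other), fish oil (84 of 100; 555, 3987), microalgae (100 of 100; 340, 3177), fish oil against microalgae (80 of 100; 590, 4071) or the fish oil interaction (90 of 100; 545, 4713). Nor was it within fish oil for maternal LPS (20 of 35; 883, 3515), within saline for fish oil (28 of 35; 441, 1152) or within maternal LPS for fish oil (29 of 35; 691, 5734). The 10 splits are too few for maternal LPS within the control diet (real 359, highest other 1484; 10 as large) and for microalgae within saline (real 563, highest other 1418; 8 as large). No splits were run for the microalgae interaction or for maternal LPS within microalgae, so chance was not tested for their counts (1118 and 2411). Random splits called a median of 4 or 5 gene lists by camera. Chance was not excluded for the 6 lists of maternal LPS (36 of 100 splits as large, highest other 13), the 7 of fish oil (33 of 100, 11), the 3 of microalgae (83 of 100, 13) and the 4 of the fish oil interaction (75 of 100, 11). For the count of 11 lists between fish oil and microalgae, 1 of 100 splits was as large, the real one, with 10 in the highest other. That share is not adjusted over the split tests made here, so it does not exclude chance. That count of gene lists called, fish oil against microalgae, was 5 without piglet 7, the median of the random splits. It was 7 without piglet 12 or 13 or with the array spread as covariate, and 0 by permutation after adjustment.

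Further differences between diets in the effect of maternal LPS, tested by the interactions, were those of macrophage markers (-0.493 for fish oil and -0.495 for microalgae), of the sensing list (-0.190 and -0.253) and of the acute inflammatory list for fish oil (-0.191). None kept its call with an estimated correlation, where the adjusted values were 0.314 and 0.935, 0.314 and 0.815, and 0.761. The fish oil and microalgae interactions share their control piglets, so their likeness is partly built in.

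Single piglets lay far from the other 3 of their group in 19 of 374 tests, where chance gives 18.7. Only the fish oil groups, with 4 piglets each, were tested, so control and microalgae offspring could not be flagged. The number for each is the gap to the nearest piglet divided by the group's range. In fish oil offspring after saline, piglet 13 was highest for the fatty acid oxidation list (0.854), SBSPON (0.9) and EIF2AK2 (0.844), and lowest for CYP21A2 (0.952) and CD2 (0.896). Piglet 18 was highest for PRR19 (0.846) and lowest for NDUFA1 (0.946) and ECSCR (0.898), piglet 11 highest for LPIN1 (0.954) and RPS16 (0.86), and piglet 9 highest for TPX2 (0.943). In fish oil offspring after LPS, piglet 24 was lowest for TLR3 (0.867), CNIH3 (0.832) and PECAM1 (0.901). Piglet 20 was lowest for IFIH1 (0.966) and highest for CHKA (0.87), piglet 10 highest for PRR19 (0.848) and SPINK5 (0.83), and piglet 19 lowest for the neutrophil list (0.874).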

How the results depend on the processing

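The array spread as covariate, the removal of the 2 most deviating arrays (piglets 6 and 24) and the permutation test of lists were chosen after the data were seen. Outside the fits without 1 piglet, 1915 values of named genes and 307 of gene lists kept their direction and side of the threshold, 55 values of lists lost their call, 1 gene gained one (IFIT2 with array weights) and 0 reversed. The count for maternal LPS was 0 without a filter, after quantile normalization, with the medulla score, with the array spread, without the 2 arrays and in the additive model, 9 with array weights and 10 at an adjusted p under 0.10. With an unadjusted p under 0.05 and a fold of 1.5, which applies no correction, it was 154, with 66 for fish oil, 60 for microalgae, 80 between them, and 386 and 961 for the fish oil and microalgae interactions. The same rule gave 126, 330 and 1529 for maternal LPS in control, fish oil and microalgae offspring, 168 and 191 for fish oil within saline and LPS, and 193 and 357 for microalgae within saline and LPS. Maternal LPS within microalgae gave 1 with only its 2 groups in the fit. Called lists numbered 2 for maternal LPS, 7 for the fish oil interaction and 1 for the microalgae interaction with the lowest 50% left out, where cell proliferation had too few members to be tested. The microalgae interaction gave 1 after quantile normalization, with the medulla score, with the array spread and with the mean of all probe sets, 4 with array weights and 7 without the 2 arrays. The fish oil interaction gave 7 with array weights and 2 with the mean of all probe sets, and fish oil against microalgae 7 with the array spread. An estimated correlation, fry and the permutation test gave 0 lists in every comparison, and fry in either direction 1 for maternal LPS and 0 elsewhere. Leaving out 1 piglet gave 0 to 12 genes for maternal LPS, 0 to 2 within fish oil, 0 to 3 within microalgae and 0 to 1 for fish oil within LPS. It gave 3 to 8 lists for maternal LPS, 5 to 10 for fish oil, 1 to 6 for microalgae, 5 to 11 between the diets, 3 to 6 for the fish oil and 1 to 7 for the microalgae interaction. Lists numbered 3 for maternal LPS without piglet 8. For microalgae they numbered 1 without 15, 5 without 16 or 22 and 6 without 23, and between the diets 5 without 7 and 7 without 12 or 13. For the microalgae interaction they numbered 7 without 6, 4 without 7 and 1 without any 1 of 12, 16, 17, 21, 22, 23 and 24. Without piglet 7, TLR3 and ATAD2 passed for maternal LPS, and TEK in the microalgae comparison turned to 0.0183, within a range from -0.44. In the comparison of fish oil and microalgae, interferon-stimulated genes ranged from -0.291 to 0.0732, above 0 without piglet 7 and, at 0.0217, without piglet 20. The medulla score, never past its test, ranged from -0.36 to 0.0371 for maternal LPS, from -0.22 to 0.37 for microalgae and from -0.48 to -0.03 for fish oil. Fits without piglet 7 or 23 leave 1 sample in its group, which is assumed to vary like the others. The causes were not tested, apart from the fewer genes or arrays that a filter or a removal leaves. Some lists were called in all 11 alternatives that keep camera's preset correlation and in all 19 fits without 1 piglet. They were interferon-stimulated and antigen presentation genes for maternal LPS, fibroblast, macrophage and oxidative phosphorylation genes for fish oil, and endothelial and oxidative phosphorylation genes between the diets. So were interferon-stimulated and macrophage genes in the fish oil interaction and macrophage genes in that of microalgae, and proliferation for maternal LPS in the 10 it could be tested in. All of these calls were lost after adjustment with an estimated correlation, by fry for a common direction and by permutation. Probe sets near background limit what can be seen, since 25% were left out as dim.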

Other observations

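Several gene groups central to an adrenal gland under challenge were called by camera in none of the 6 comparisons, among them steroid synthesis, ACTH signalling, glucocorticoid targets, immediate early and heat shock genes. After maternal LPS, the 16 genes of cortical steroid synthesis had a mean difference of -0.04 ± 0.0369 log2 and the 18 genes of ACTH and cAMP signalling, which drives cortisol output, one of -0.08 ± 0.036 (camera adjusted p 0.612 and 0.221). Glucocorticoid receptor targets, 28 genes that respond to cortisol, had a mean of -0.01 ± 0.0335, and the median of this list (0.00468) differed in sign from its mean and its test. The cortisol-induced gene FKBP5 had 7.45 ± 0.296 and the receptor NR3C1 5.49 ± 0.292 over all piglets (SD, n = 19). Immediate early genes (-0.07 ± 0.0347), heat shock genes (-0.03 ± 0.0256), antioxidant genes (-0.08 ± 0.0363), oxidative phosphorylation genes (-0.05 ± 0.0285) and ribosomal proteins (0.05 ± 0.0199) were not called for maternal LPS, although the last 3 were called in diet comparisons. Among lipid genes, neither the 27 of polyunsaturated fatty acid and eicosanoid metabolism (-0.07 ± 0.0347), nor the 27 of fatty acid oxidation (-0.05 ± 0.0344), nor the 11 of lipogenesis (-0.11 ± 0.0611) were called for maternal LPS. Fatty acid oxidation genes were called for fish oil and between fish oil and microalgae. The lipogenic malic enzyme ME1, chosen after its values were seen, fell (-0.37 ± 0.108, adjusted over the list alone 0.0372). FADS2, the first desaturase of polyunsaturated fatty acids, had 9.71 ± 0.231 over all piglets, with differences of 0.19 ± 0.131 for fish oil and 0.09 ± 0.148 for microalgae.

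Cell type markers were not called for maternal LPS. Means were -0.01 ± 0.034 for macrophage markers, 0.05 ± 0.0241 for lymphocyte markers, -0.01 ± 0.0279 for endothelial markers and 0.09 ± 0.0691 for neutrophil markers. Of the neutrophil markers, S100A9, chosen after its values were seen, was higher (0.32 ± 0.0963, adjusted over the list alone 0.0364). Adjusted over the acute inflammatory list, which also holds it, the value was 0.178, and over all probe sets 0.498. Fibroblast markers had -0.02 ± 0.0678, with a median of 0.04 and a test in the direction of the median. Zona glomerulosa and capsule signalling genes had -0.06 ± 0.0368 and chromaffin cell genes -0.13 ± 0.0515 (camera adjusted p 0.612 and 0.0948). Schwann and sustentacular (0.05 ± 0.0479), adipocyte (0.07 ± 0.0338) and erythroid markers (0.10 ± 0.0699) completed the cell types. Kidney markers, included because the organs adjoin, had -0.02 ± 0.0339 with a mean level of 4.11 log2 over their 8 genes. In the microalgae interaction SLA-DRB1, a class II antigen presentation gene, changed (1.68 ± 0.394, adjusted over the list alone 0.0104), in a list that was not called.

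The lists share few members. Interferon-stimulated and antigen presentation genes share 3, the acute inflammatory list shares 3 with neutrophil markers and 3 with glucocorticoid targets, and fatty acid oxidation shares 3 with glucocorticoid targets. Many members of the leucocyte, vessel and connective tissue lists are expressed by cells that an adrenal gland normally holds.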
